A study of Mus musculus with 6 samples.

How the data were processed

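Total RNA from the pancreas of 4-week-old mice of a mixed genetic background was profiled on 6 single-colour oligonucleotide arrays, 3 from control and 3 from pre-cancerous pancreas. Per the labels' protocols, RNA was extracted from fresh tissue by the Chirgwin method and labelled with biotin. Both groups carried floxed Ink4a/Arf alleles and a silent Kras allele (G12D) behind a lox-stop-lox cassette, and the pre-cancerous group also carried the Pdx1-Cre transgene, which drives Cre recombinase in the pancreas. The labels give all 6 animals as male. Groups and sample numbers were taken from the labels, whose source names call the pre-cancerous samples tumor pancreas. The labels do not say that the samples of a group came from separate animals or litters, so the p-values measure the spread between these samples.

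The main data were the deposited log2 expression values, 1 per probe set and array, for 34760 probe sets. The submitters' processing notes name the affy package, without a version. The background correction, normalization and summary steps are not given in the sources used here. The values were on a log2 scale, were not centred on genes or on controls, and had medians over all probe sets of 6.70, 6.70 and 6.73 on control arrays 1 to 3 and 6.80, 6.74 and 6.78 on pre-cancerous arrays 1 to 3. A second deposited table held log2 ratios for 21794 gene identifiers in each array. Its scale was worked out from the values: the linear values of the 3 control columns average 1 in every row, so each entry is the log2 ratio of an array to the arithmetic mean of the controls. After the same ratio was formed from the main table, the lowest column correlation between both tables was 0.968. The ratio table was used as an alternative source and for genes that the main table does not name.

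Probe sets were named through the platform annotation, with symbols looked up by gene identifier in a current reference gene table, which changed 0 symbols. Of the probe sets, 21640 had 1 gene symbol, 1321 had several, and 11799 were not listed in the annotation and are unnamed here. Probe sets with 1 symbol were kept, and each of 19937 genes was represented by its probe set with the highest mean over all 6 arrays; 954 genes had more than 1 probe set. No filter on dim probe sets was applied in the main test. No scan date, slide or batch was given for any array. The number of arrays limits the precision of every value.

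Pre-cancerous and control arrays were compared gene by gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariates), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Errors of log2 fold changes are the moderated standard errors. Of 50 gene lists fixed before the data were examined, 47 were tested with limma's camera at its preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Lists with fewer than 5 measured genes (the erythroid list) were not tested, and the targeted loci and the sex-linked genes served as label checks. Camera with a correlation estimated per list and the directional fry test were alternatives. Member counts are given over all genes and adjusted over the list alone. List medians per array are medians over genes of the array's log2 value minus the control mean. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1.

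The genes to be named were set by a rule fixed beforehand: up to 12 called genes with the largest increase and 12 with the largest decrease whose groups did not overlap, leaving out immunoglobulin and T cell receptor segments and unnamed loci; Kras, Cdkn2a and Cdkn2b; and for each list up to 4 called members with the largest change, or the 2 with the largest change where none was called. Genes outside this rule are marked as chosen after their values were seen.

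The gene test was tested on simulated data of 19937 genes. With the spread of the control arrays it called 75 of 100 genes changed by 1 log2 unit and 94 of 100 changed by 2, and with the spread of both groups 43 and 87 of 100. Of the unchanged genes, 12 were called with the first spread and 7 with the second. For lists, all 10 of 10 lists shifted by 0.5 log2 units were called, and 1 of 10 unshifted lists was called as well. The simulated genes were independent, with the spread of the control arrays. In the data, the correlation estimated within called lists ran from 0.020 (duct cells) to 0.99 (acinar enzymes). The simulation therefore does not give the error rate of the list calls here.

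Alternatives were quantile normalization, median centring over listed probe sets or over genes in no list, the ratio table, leaving out the 40 percent dimmest probe sets, an intensity trend with and without a robust prior, array weights, the mean of a gene's probe sets, each probe set on its own, 2 other thresholds, each array left out in turn, the sample number as a block, and, for lists, genes of 2 lists left out. Leaving out genes on chromosomes X and Y, the lists on the ratio table, and an estimated list correlation without pre-cancerous array 1, were added after the data were seen. A change of pseudocount did not apply, since the values were already on a log scale.

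Bootstrap intervals of list medians are 95% intervals over 2000 resamplings of genes. For listed genes matched on their control mean, fewer resamplings were used. To set the groups against chance, the gene and list tests were run on all 10 splits of the 6 arrays into 3 and 3. The neighbours of Ppy, 10 measured genes to each side without Pyy, were set against 2000 runs of neighbouring genes drawn at random.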

Results

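Expression was measured in whole pancreas of 4-week-old mice carrying floxed Ink4a/Arf and lox-stop-lox Kras (G12D) alleles, without Cre (control, n = 3 arrays) or with the Pdx1-Cre transgene (pre-cancerous, n = 3 arrays). Kras encodes a small GTPase of growth factor signalling, and the Ink4a/Arf locus, Cdkn2a, encodes tumour suppressor proteins. Per the series' title the pre-cancerous tissue is from a mouse model of pancreatic ductal adenocarcinoma. The source names of these samples read tumor pancreas, and no histology was used here. The comparison asks which transcripts differ between the groups at 4 weeks of age. Levels are log2 values as normalized by the authors.

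Of the targeted genes, Cdkn2a and Cdkn2b overlapped between the groups and Kras did not, and none was called. Cdkn2a was at 6.69, 6.99 and 7.01 in the controls and at 6.91, 6.79 and 6.67 in the pre-cancerous arrays, a log2 fold change of -0.11 (SE 0.13, n = 3 per group, limma adjusted p = 0.675). Where its probes lie relative to the floxed segment is not given in the sources used here, so this level does not check the labels. The neighbouring Cdkn2b, a related cell cycle inhibitor, was at 9.48 in pre-cancerous array 1 and between 6.79 and 7.18 in the other 5 arrays (log2 fold change 0.87, SE 0.64, limma adjusted p = 0.539). Kras was named only in the ratio table, where its log2 ratios to the control mean were -0.04, 0.20 and -0.18 in the controls and 1.77, 0.30 and 0.28 in the pre-cancerous arrays (limma adjusted p = 0.52). These totals do not tell the mutant transcript from the wild type.

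Sex-linked genes, a label check fixed before the data were examined, went against the label of pre-cancerous array 3, which is labelled male. Xist, the transcript of the inactive X chromosome, was at 11.57 in that array and between 4.66 and 5.40 in the other 5. The Y-linked genes Eif2s3y, Uty and Kdm5d were at 4.22, 4.22 and 5.16 in that array, and in the others at no less than 8.52, 7.80 and 7.12. The array labelled male was kept in its group. Whether its sex label is wrong or the sample was exchanged for one from outside these 6 is not known, and its genotype was not checked by any gene here. Leaving out genes on the X and Y chromosomes left 1 gene called. Leaving out the array left 0 genes and all 29 of the lists called below.

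Pre-cancerous array 1 stood apart from the other 5 arrays. Its mean correlation with the controls across genes was 0.877, against 0.9896 for pre-cancerous array 2, 0.982 for array 3 and 0.9895 among the controls; genes are not independent replicates. The first principal component held 81.1% of the variance and placed array 1 at 102.8, with the other 5 between -30.7 and -0.67. In that array a mean of 1898 genes lay at least 1 log2 unit above a pair of controls and 984 as far below, against 33 and 15 in array 2 and 176 and 34.7 in array 3; each control, set against the other pair, had 8 to 29 above and 4 to 30 below. Values below are given per array.

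A single gene, Ppy, was called between the groups. Ppy encodes pancreatic polypeptide, the hormone of the islet PP cells, and rose in all 3 pre-cancerous arrays, from 9.60, 9.41 and 9.22 in the controls to 11.92, 12.02 and 12.06, a log2 fold change of 2.59 (SE 0.13, 6.00-fold, limma adjusted p = 0.0146). With its neighbour and relative Pyy, which encodes peptide YY and was chosen after its values were seen, it was called among the 17 measured islet genes when adjusted over the list alone (2 higher, 0 lower). Pyy had a log2 fold change of 1.51 (SE 0.24, adjusted p = 0.521 over all genes). The call of Ppy was lost without control array 1 (adjusted p = 0.0928), control array 2 (0.331), control array 3 (0.125), pre-cancerous array 2 (0.0651) or pre-cancerous array 3 (0.254), each with a log2 fold change of at least 2.49.

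Of the 19937 genes tested, 1 was called higher and 0 lower, while 1506 had an unadjusted p under 0.05 (710 higher and 796 lower). The pre-cancerous and control values did not overlap for 1852 higher and 2325 lower genes, 20.95% of all, where chance gives 10% on average. Genes vary together, so the share in a single grouping can lie far from that average. It was not counted in the other splits. The median spread within a group was 0.130 (SD) in the controls and 0.191 in the pre-cancerous arrays. Several genes chosen after their values were seen were at like levels in all 3 pre-cancerous arrays without passing the adjustment. Lyz1, a lysozyme of Paneth cells, was at 9.58, 9.46 and 9.51 against 7.85, 7.65 and 7.34 in the controls (adjusted p = 0.123), and Camk2b, a calcium-dependent kinase subunit, was at 7.65, 7.88 and 7.63 against 9.26, 8.84 and 9.18 (adjusted p = 0.521). Without pre-cancerous array 1, 4 genes were called higher by limma: Gkn2 (log2 fold change 3.53, SE 0.14, adjusted p = 0.000249), Ppy (2.62, SE 0.13, adjusted p = 0.00102), Lyz1 (1.87, SE 0.16, adjusted p = 0.0253) and Pyy (1.74, SE 0.16, adjusted p = 0.0354). Without pre-cancerous array 2, 2 other genes, also chosen after their values were seen, were called: Glycam1, a mucin-like ligand of high endothelial venules (4.99, SE 0.11, adjusted p = 0.0013), and the gastric gland mucin Muc6 (4.13, SE 0.19, adjusted p = 0.0255).

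**Figure D1:**
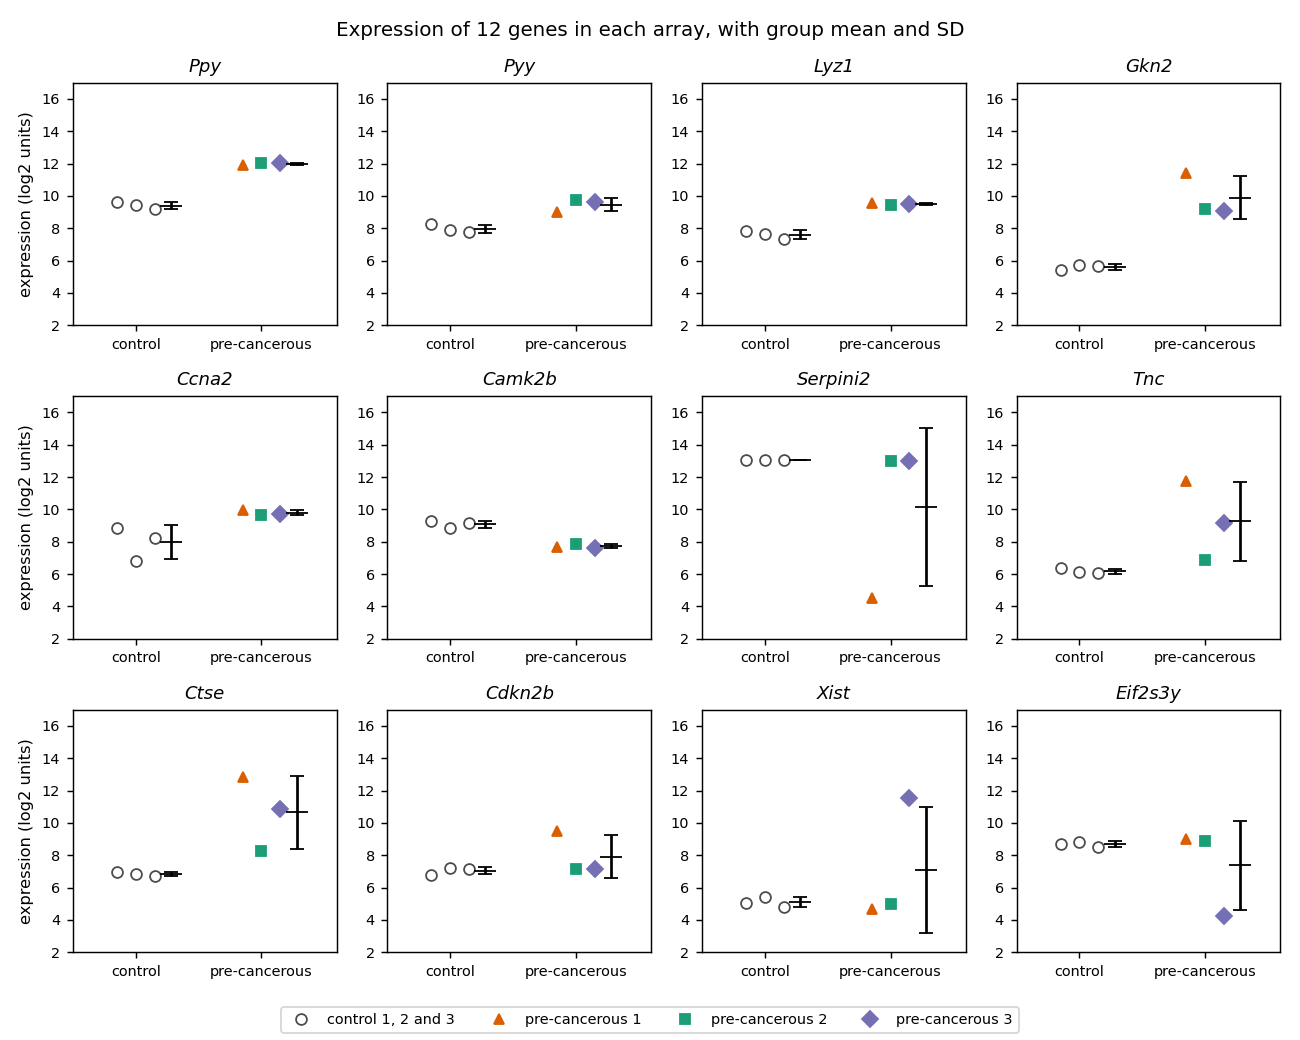
Expression in log2 units (vertical axes) of 12 genes in each of the 6 arrays, with open circles for the 3 controls, filled symbols for the 3 pre-cancerous arrays, and bars for the group mean and SD. Ppy lies at 11.92 to 12.06 in the pre-cancerous arrays and 9.22 to 9.60 in the controls, Serpini2 is low (4.51) only in pre-cancerous array 1 among the 6, and Xist is high (11.57) only in pre-cancerous array 3.

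Of the 47 lists tested with camera at its preset correlation, 20 were called higher and 9 lower. Those calls rest on that preset: 0 lists were called with a correlation estimated from the arrays (smallest adjusted p = 0.583 with an estimated correlation, smallest unadjusted p = 0.033) and 0 by fry (smallest adjusted p = 0.284), and other splits of the same 6 arrays gave 18 to 30 called lists. Below, a list "rose" or "fell" at the preset correlation only. Of the 29 called lists, 21 kept their call and direction without pre-cancerous array 1. There too, 0 were called with an estimated correlation (smallest adjusted p = 0.413).

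The cell cycle and mitosis list rose, with medians in each pre-cancerous array above those of all controls. All 36 measured members had a positive log2 fold change, and the list median was 1.18, 0.94 and 0.65 above the control mean in pre-cancerous arrays 1 to 3, with 0.43, -0.46 and -0.07 in the controls (camera adjusted p = 1.47e-23, adjusted p = 0.583 with an estimated correlation). Over all genes 0 members were called. Of them, 24 were higher when adjusted over the list alone. Ccna2, a cyclin of S phase and mitosis, was at 9.97, 9.68 and 9.72 against 8.85, 6.81 and 8.25, and the spindle checkpoint kinase Bub1 at 8.27, 7.42 and 7.39 against 6.57, 5.43 and 5.73 (log2 fold changes 1.82, SE 0.50, and 1.79, SE 0.37, both adjusted p = 0.521). Without pre-cancerous array 1 the median log2 fold change was 0.78, against 0.87 with all arrays.

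The list of gastric-type metaplasia and PanIN (pancreatic intraepithelial neoplasia) markers rose, with medians of 2.10, 0.25 and 0.82 in pre-cancerous arrays 1 to 3 and -0.05, 0.01 and 0.05 in the controls (camera adjusted p = 3.58e-07, adjusted p = 0.583 with an estimated correlation). Its median log2 fold change was 1.10 over 21 genes, and 0.59 without array 1. Adjusted over the list alone, 8 members were higher and 1, Vsig2, was lower (log2 fold change -0.48); over all genes 0 were called. Gkn2, which encodes a gastrokine of the stomach lining, was at 11.43, 9.20 and 9.07 against 5.40, 5.74 and 5.70 (log2 fold change 4.29, SE 0.63, adjusted p = 0.521), and the aspartic protease Ctse at 12.82, 8.28 and 10.84 against 6.99, 6.84 and 6.74 (3.79, SE 1.07, adjusted p = 0.521). The other members higher over the list alone, Muc5ac, Muc6, Tff1, Cldn18, Gkn1 and Pgc, chosen after their values were seen, had log2 fold changes of 0.58 to 2.96. The duct cell list rose by a median of 0.32 (camera adjusted p = 0.00162, adjusted p = 0.583 with an estimated correlation), with 0.52, 0.29 and 0.26 in the 3 arrays, and by 0.51 without control array 1. Its members with the largest changes, the keratin Krt7 and the chloride channel Cftr, were high in pre-cancerous array 1 (10.96 and 8.96) at 7.59 and 5.21 in array 2, and at 8.32 and 6.31 in array 3, against control means of 7.47 and 5.36.

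Acinar lists fell, with low values in pre-cancerous array 1 only. The list of digestive enzymes and secretory proteins had medians of -5.51 in that array and of 0.0060 and -0.01 in pre-cancerous arrays 2 and 3 (28 genes, all with a negative log2 fold change, camera adjusted p = 0.000223, adjusted p = 0.616 with an estimated correlation). Serpini2, a pancreatic serpin, was at 4.51 in array 1 and 12.98 in array 2, against 13.07, 13.03 and 13.07 in the controls, and the zymogen granule protein gene Zg16 at 5.89, 13.50 and 13.49 against 13.57, 13.46 and 13.61. The acinar transcription factors had medians of -2.10, -0.0095 and -0.02 (camera adjusted p = 0.0429, adjusted p = 0.616 with an estimated correlation). Bhlha15 (Mist1), which drives secretory granule maturation, was at 6.84 in array 1 against a control mean of 11.69, and Ptf1a, the acinar master regulator, at 5.96 against 10.02. Without array 1 neither list was called (adjusted p = 0.412 with a median of -0.0028 for the enzymes, and 0.933 with 0.0012 for the transcription factors); the transcription factor call was also lost without control array 1 (0.143) or control array 3 (0.0672). Its median log2 fold change of -0.72 was -1.09 without array 2. The regeneration list, which holds the Reg genes, was not called (median 0.13, mean -0.18, adjusted p = 0.291), and Reg3a and Reg3d were at 6.11 and 6.55 in array 1 against control means of 13.19 and 13.36.

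The islet list was not called with all arrays (median -0.11, mean 0.10, tested direction up, adjusted p = 0.289). Its medians were -0.69, 0.17 and 0.45 in pre-cancerous arrays 1 to 3. Without array 1 it was called higher, with a median of 0.34 (adjusted p = 1.16e-06, adjusted p = 0.413 with an estimated correlation). Glucagon (Gcg) and insulin 2 (Ins2) were chosen after their values were seen. Gcg was at 10.11, 12.67 and 12.73 against 12.04, 12.39 and 11.41, and Ins2 at 9.56, 9.87 and 9.85 against 9.73, 9.71 and 9.65.

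Stromal lists rose, most of all in array 1 among the 3. Extracellular matrix and its crosslinking had medians of 1.83, 0.29 and 0.67 (37 genes, 36 with a positive log2 fold change, camera adjusted p = 1.87e-14), fibroblasts and stellate cells 1.66, 0.17 and 0.63 (adjusted p = 7.57e-07), EMT (epithelial-mesenchymal transition) genes 2.16, 0.14 and 0.51 (adjusted p = 0.000146) and endothelial cells 0.50, 0.22 and 0.31 (adjusted p = 2.68e-06). All 4 had an adjusted p = 0.583 with an estimated correlation, and 0 of their members were called over all genes or adjusted over the list alone. Without array 1 their median log2 fold changes went from 0.87, 0.81, 0.93 and 0.39 to 0.48, 0.39, 0.30 and 0.24. The highest control medians of these lists were 0.14, 0.15, 0.17 and 0.17. The array 2 median lay below this value for EMT genes and above it for the others. Tenascin C (Tnc) was at 11.78, 6.88 and 9.15 against 6.36, 6.11 and 6.09, the metalloprotease inhibitor Timp1 at 12.05, 6.62 and 8.32 against 6.22, 6.22 and 6.21, and collagen Col1a1 at 11.99, 9.71 and 10.45 against 9.57, 9.15 and 9.24. Fibronectin (Fn1) was at 13.47, 10.95 and 12.06 against 10.72, 9.99 and 10.46, a log2 fold change of 1.77 (SE 0.62) that was 1.11 without array 1. The endothelial genes Cdh5 and Egfl7 had log2 fold changes of 0.66 (SE 0.21) and 0.64 (SE 0.17), and all 3 genes had adjusted p = 0.521.

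The immune lists given here, mast cells not among them, rose. Each had its highest pre-cancerous median in array 1 and its lowest in array 2. The highest control medians were 0.18 for macrophages, 0.05 for T and NK cells, 0.13 for B cells and 0.65 for MHC class II. They were 0.19 for interferon, 0.12 for neutrophils, 0.07 for cytokines and 0.13 for complement. Array 2 lay above the highest control median for MHC class II only, and array 3 lay below it for neutrophils and complement. Of the 19 interferon genes, 0 had all 3 pre-cancerous values above all controls. Macrophages and monocytes had medians of 3.13, 0.15 and 0.80 (camera adjusted p = 1.88e-07), T and NK cells 1.96, 0.01 and 0.57 (adjusted p = 1.03e-05), B and plasma cells and lymph node 2.25, -0.16 and 1.02 (adjusted p = 6.6e-05), MHC class II genes 3.16, 0.78 and 1.46 (adjusted p = 0.000111) and the type I interferon response 1.51, 0.04 and 0.22 (adjusted p = 7.89e-05); all 5 had an adjusted p = 0.583 with an estimated correlation. Their median log2 fold changes of 1.31, 0.80, 0.99, 1.84 and 0.59 were 0.52, 0.32, 0.40, 1.10 and 0.19 without array 1. Without array 2 the first 3 were 1.98, 1.27 and 1.61, and without control array 3 the interferon list was 0.38. Of the MHC class II genes 5 of 6 were higher when adjusted over the list alone, among them H2-Ab1 (12.11, 9.74 and 10.52 against 9.64, 8.90 and 8.13), and 0 over all genes. Laptm5, a lysosomal protein of leukocytes, was at 12.23, 9.15 and 10.45 against 8.86, 8.11 and 8.32, the T cell receptor component Cd3g at 9.15, 5.16 and 7.09 against 5.33, 5.08 and 4.97, and the B cell receptor component Cd79b at 10.46, 6.79 and 9.20 against 7.20, 7.02 and 7.21. Beside the B cell and lymph node list, Glycam1 of high endothelial venules, chosen after its values were seen, was at 10.68, 5.64 and 10.63 against 5.65, 5.59 and 5.75. Neutrophils (2.11, -0.22 and 0.05, adjusted p = 0.00332), cytokines and chemokines (1.84, -0.03 and 0.14, adjusted p = 0.000143) and complement and coagulation (1.27, 0.03 and 0.10, adjusted p = 0.00587) rose as lists with all arrays and were not called without array 1, with adjusted p = 0.518, 0.146 and 0.18 and medians of -0.04, 0.08 and 0.12. Their adjusted p with an estimated correlation was 0.603, 0.6 and 0.583. The complement call was also lost without control array 3 (0.0893). The neutrophil and cytokine medians of 0.65 and 0.58 were 1.18 and 0.93 without array 2.

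Among signalling lists, the MAPK output of KRAS, genes induced by the pathway downstream of that GTPase, rose with medians of 1.33, 0.14 and 0.16 (25 genes, camera adjusted p = 7.57e-07, adjusted p = 0.583 with an estimated correlation), and its median log2 fold change of 0.58 was 0.18 without array 1. The ETS factor Etv1 was at 9.08, 8.19 and 8.50 against 7.99, 7.05 and 7.09. Notch signalling rose with medians of 0.49, 0.12 and 0.14 (adjusted p = 0.000397, adjusted p = 0.583 with an estimated correlation), with a median log2 fold change of 0.23, and 0.15 without array 1. Prostaglandin and leukotriene synthesis rose with medians of 1.46, 0.0038 and 0.30 (adjusted p = 0.00171, adjusted p = 0.583 with an estimated correlation), and its median of 0.53 was 0.08 without array 1 and 0.89 without array 2. The macrophage list (3.13, 0.15 and 0.80) and the T and NK cell list (1.96, 0.01 and 0.57) had the same order of arrays. The control medians of the prostaglandin list were 0.04, 0.01 and -0.08, so array 2 lay within them. Thromboxane synthase (Tbxas1) was at 8.93, 7.32 and 7.65 against 6.60, 6.60 and 6.18. None of these lists had a called member.

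Among metabolic lists, oxidative phosphorylation fell, with medians in each pre-cancerous array below those of all controls. Its medians were -0.69, -0.15 and -0.17, with -0.05, 0.01 and 0.04 in the controls, and 60 of 61 measured members had a negative log2 fold change (camera adjusted p = 1.12e-10, adjusted p = 0.583 with an estimated correlation). Its median log2 fold change was -0.33, and -0.14 without array 1. Ribosomal protein genes had a median of -0.58 in array 1, so the fall in that array was not particular to this list. Their medians in arrays 2 and 3 were not computed. Ndufa1, a subunit of respiratory complex I, was at 6.89, 7.92 and 7.89 against 8.40, 8.48 and 8.39, a log2 fold change of -0.86 (SE 0.29) that was -0.52 without array 1. Uqcrq, a subunit of complex III, was at 8.36, 9.998 and 9.64 against 10.16, 10.38 and 10.46, and both genes had adjusted p = 0.521. Fatty acid oxidation and ketogenesis fell with medians of -0.45, -0.11 and -0.12 (adjusted p = 0.00845) and the TCA cycle with -0.24, -0.06 and -0.10 (adjusted p = 0.0186), both with adjusted p = 0.583 with an estimated correlation; the first list's median log2 fold change was -0.21, and -0.11 without array 1. Serine, glycine and one-carbon metabolism fell with medians of -2.02, -0.02 and -0.14 (adjusted p = 0.00195, adjusted p = 0.603 with an estimated correlation), and its median of -0.74 was -0.10 without array 1 (adjusted p = 0.0302). The control medians of this list were -0.02, -0.05 and 0.08, so array 2 lay within them. Its members Mat1a and Gnmt, enzymes of methionine metabolism, were at 5.74, 10.47 and 10.17 and at 6.27, 9.87 and 10.48 against control means of 10.64 and 10.59. The acinar enzyme list was lowest in the same array, with medians of -5.51, 0.0060 and -0.01. Adipocyte markers fell with medians of -0.57, -0.57 and -0.21 (camera adjusted p = 0.0032, adjusted p = 0.583 with an estimated correlation). The control medians of this list were 0.20, -0.20 and -0.03, so array 3 was close to control array 2. Adiponectin (Adipoq) was at 6.45, 5.89 and 6.53 against 8.25, 6.78 and 7.08.

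Glycolysis rose with medians of 0.83, 0.07 and 0.08 (adjusted p = 0.00347, adjusted p = 0.583 with an estimated correlation), and was not called without array 1 (adjusted p = 0.158, median 0.08). The macrophage list (3.13, 0.15 and 0.80) and the fibroblast list (1.66, 0.17 and 0.63) were also highest in array 1. The glucose transporter Slc2a1 was at 11.45, 9.47 and 9.64 against 9.32, 9.39 and 9.09. Aminoacyl-tRNA synthetases (-0.96, 0.0028 and -0.01, adjusted p = 0.0299, adjusted p = 0.625 with an estimated correlation) and glutamine, asparagine, arginine and proline metabolism (-1.25, -0.03 and -0.06, adjusted p = 0.0476, adjusted p = 0.603 with an estimated correlation) fell as lists, and neither was called without array 1 (both adjusted p = 0.634, medians -0.02 and -0.03). For these lists too the lowest median was in array 1, that of the low acinar list (-5.51). The synthetases were not called without control array 1 (0.204), and their median of -0.32 was -0.49 without array 3. The amino acid list was not called without control array 1, 2 or 3 (0.0803, 0.0621 and 0.0727). Cholesterol synthesis rose with medians of 0.04, 0.31 and 0.06 (adjusted p = 0.00347, adjusted p = 0.583 with an estimated correlation). Its median log2 fold change of 0.12 was 0.24 without array 1, 0.02 without array 2 (adjusted p = 0.228, not called) and 0.23 without array 3. Msmo1, a sterol oxidase, was at 9.10, 8.73 and 8.44 against 8.17, 8.13 and 8.18.

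**Figure D2:**
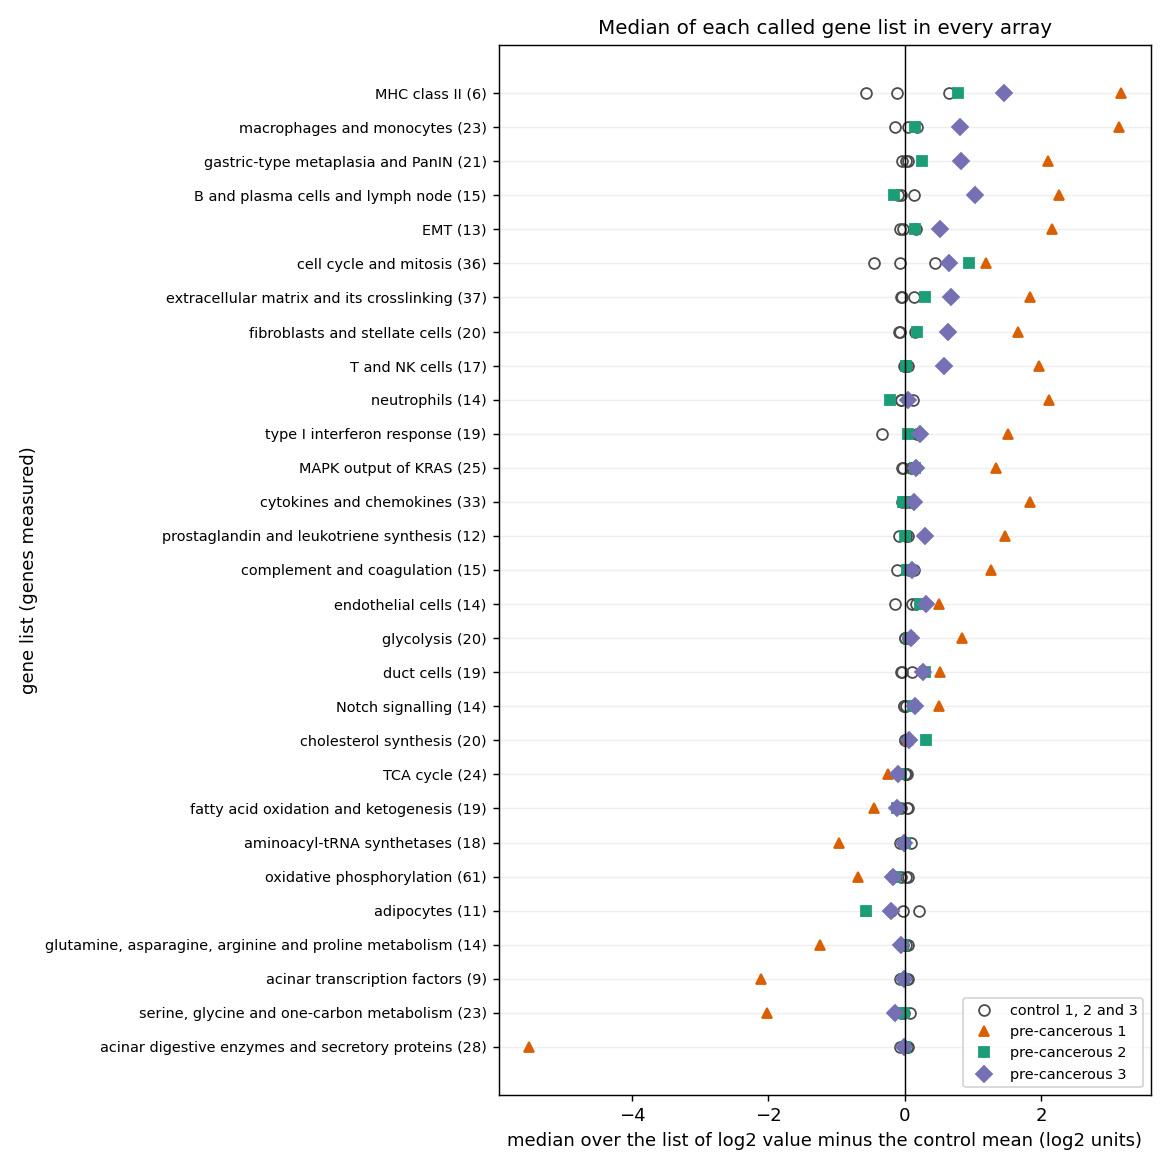
Median of each of the 29 called lists in every array (horizontal axis, log2 value minus the control mean; vertical axis, list with its number of measured genes), with open circles for the 3 controls and filled symbols for the 3 pre-cancerous arrays. The acinar enzyme list lies at -5.51 in pre-cancerous array 1 and within 0.02 of 0 in the other pre-cancerous arrays, while the cell cycle list lies above all 3 controls in each pre-cancerous array (0.65 to 1.18).

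The remaining lists were not called with all arrays. Lipoprotein uptake and sterol handling (median 0.58, adjusted p = 0.0569), lysosome and autophagy (0.08, 0.0741), tuft cells (0.09, 0.291), hexosamine pathway and sialic acid (0.03, 0.455), NRF2 targets and antioxidant enzymes (0.18, 0.494) and the hypoxia response (0.04, 0.522) had positive median log2 fold changes. Mesothelium (median -0.24, adjusted p = 0.0915), ER chaperones and the unfolded protein response (-0.37, 0.112), fatty acid and glyceride synthesis (-0.11, 0.291), the pentose phosphate pathway (-0.22, 0.346), amino acid transporters (-0.14, 0.915) and mast cells (-0.06, 0.984) had negative ones. Without pre-cancerous array 1 the medians of the lipoprotein list and the pentose phosphate pathway were 0.08 and -0.10. The median, mean and tested direction differed in sign for nucleotide synthesis (median -0.06, mean 0.07, adjusted p = 0.517), Schwann cells and nerve (-0.07, 0.08, 0.521), intestinal epithelium (-0.07, 0.06, 0.563) and p53 targets (-0.02, 0.03, 0.984). Of the ER chaperone genes, the pancreatic isomerase Pdia2 was at 5.28 in pre-cancerous array 1 and at 12.97 and 13.01 in arrays 2 and 3, against a control mean of 13.08. Of 10 erythroid genes, 4 were measured, with a median of -0.03 and no test.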

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

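The tests below were chosen after the patterns were seen, except the counts over other splits of the arrays. Further signals lay outside the genes compared above. Among 13120 probe sets without a single gene name, 0 were called by limma, and 11 had all 3 pre-cancerous values at least 1 log2 unit above every control, against 1 that lay as far below. One of them lists several Sprr2 genes of the cornified envelope (12.57, 8.66 and 8.92 against 7.33, 7.31 and 7.44), and the largest fold change among them belonged to probe set 10414262 (9.50, 8.24 and 8.98 against 6.08, 5.28 and 5.56), which is unnamed here. Among 1606 genes named only in the ratio table, 3 met the same rule and 0 the opposite one: Ear2 and Ear10, eosinophil-associated ribonucleases, with log2 ratios of 3.79, 2.51 and 3.25 and of 2.90, 1.41 and 3.62, and Sprr2a1 with 4.94, 1.23 and 1.40 (each adjusted p = 0.52). Ear2 ran in parallel with probe set 10414262, also in the controls (0.41, -0.42 and -0.11), with log2 fold changes of 3.22 and 3.26. Sprr2a1 is among the genes that the Sprr2 probe set lists (2.53 and 2.69). Each pair may be 1 signal read in both sources, so they are not counted as separate findings.

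Of those 11 probe sets, most have numbers below any listed in the annotation. The 6573 probe sets of that range were higher in the pre-cancerous arrays as a set. Whether these probe sets measure genes or are controls of the array is not given in the sources used here. The shift is therefore not read as a change in gene expression. Their array medians were 5.89, 5.86 and 5.84 in the controls and 6.19, 6.01 and 6.30 in the pre-cancerous arrays. Of them, 17.8% had all 3 pre-cancerous values above the controls and 5.22% all 3 below, where chance gives 5% each way on average. Probe sets vary together, and these shares were not counted in other splits. The median log2 fold change of 0.17 was still 0.109 under the lower of quantile normalization and median centring. Both were applied to the deposited values, so the submitters' own normalization was not undone and stays open as a cause. Listed genes matched on their control mean had a median of -0.0625 (95% bootstrap interval -0.0665 to -0.0582), which argues against a shift of all dim signals. The matched genes were drawn with replacement, so this interval can be too narrow. A difference in hybridization or scan cannot be told apart from the groups, since 0 batches holding both groups are known, and the genotype stays open as well.

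The loss of acinar transcripts in pre-cancerous array 1 was weighed against 3 technical explanations. The islet list had a median of -0.69 there (95% bootstrap interval -1.29 to -0.137), far less than the acinar list (-5.51, -6.61 to -4.89), which argues against tissue other than pancreas in place of pancreas. Ribosomal protein genes had a median of -0.58 (-0.82 to -0.436), a far smaller fall than that of the acinar list. This argues against a loss shared alike by all abundant transcripts as the cause of the acinar fall. That interval is wholly negative and the values were already normalized, so a lower quality of this array stays open. The acinar median moved by no more than 0.155 under quantile normalization or median centring. Both were applied to the deposited values, so the submitters' own normalization was not checked. A selective loss of acinar RNA in handling and a loss of acinar identity with the genotype both stay open, untested.

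The rise of Ppy was weighed against 3 explanations. The other islet genes had a median log2 fold change of -0.108 (95% bootstrap interval -0.257 to 0.0909), below the 1 log2 unit set as the mark of a larger share of islet tissue. Array 1 lowered it: the islet list, Ppy included, had medians of -0.69, 0.17 and 0.45 in pre-cancerous arrays 1 to 3. Without array 1 the list's median log2 fold change was 0.34, still below that mark, while that of Ppy was 2.62. A larger share of the glucagon-poor pancreas head would lower Gcg, and Gcg was 0.285 above the highest control in the lower of pre-cancerous arrays 2 and 3, an excess smaller than the SD of the controls (0.49), and at 10.11 in array 1, below the lowest control (11.41), so this explanation stays open. The 19 measured neighbours of Ppy had a median absolute log2 fold change at percentile 75.5 of runs of neighbouring genes, so a chromosome segment of another strain in this mixed background cannot be told apart from an effect of the genotype. Its single call came with 1 gene in the real split of the arrays and at most 0 in the other splits, and the 29 called lists with at most 30 in the others; 2 of the 10 splits gave as many lists and 1 as many genes, and 10 splits are too few for a share under 0.05.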

How the results depend on the processing

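Leaving out X and Y genes, the lists on the ratio table and the estimated correlation without pre-cancerous array 1 were chosen after the data were seen. Ppy was called under quantile normalization, both median centrings, the ratio table, the dim filter, both intensity trends, the mean of probe sets, single probe sets, a log2 fold change of at least 1 and without X and Y genes (adjusted p 0.00695 to 0.0442 where recomputed over genes). At an adjusted p under 0.01, 0 genes were called. With array weights 1364 genes were called higher and 1522 lower, but the weights did not converge and gave pre-cancerous array 3 a weight of 26.2 against 0.107 for array 1, so that fit follows mainly 1 array. Leaving out each array in turn gave 0 to 4 genes called higher and 5 to 10 lists called lower. With the sample number as a block, 0 genes were called higher (Ppy adjusted p = 0.527) and 20 lists higher and 9 lower; same-numbered samples deviated together with correlations of 0.114, 0.0014 and 0.103, so the numbers were not taken as pairing. An estimated correlation gave 0 lists higher and 0 lower, as did fry. The median log2 fold change of all genes was -0.04, and -0.11 and -0.10 after the 2 median centrings. Without the 40 percent dimmest probe sets the mean correlation among controls was 0.9754, and of pre-cancerous arrays 1 to 3 with them 0.6496, 0.9746 and 0.9555; the cause was not tested.

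Of the named genes under the alternatives, 1568 values kept direction and side of the threshold, 39 passed it (38 with array weights), 6 lost it (all Ppy) and 9 turned. Array weights turned Cpa3 (0.15), Asns (0.0038), Arg2 (0.14), Slc38a5 (0.034) and Tars (0.060). Leaving out each array gave ranges of -0.69 to 0.075 for Cpa3, -1.41 to 0.032 for Asns, -1.39 to 0.038 for Arg2 and -2.45 to 0.0027 for Slc38a3, turned without pre-cancerous array 1; none was called. Of the list results, 719 kept direction and side, 85 lost the call, 13 gained it and 27 turned the tested direction, in some cases without a change in the sign of the median; of the called lists, neutrophils and aminoacyl-tRNA synthetases turned, without pre-cancerous array 1. The acinar transcription factors and the glutamine list lost their call under quantile normalization (adjusted p = 0.0555 and 0.0717) and, with the synthetases, under both median centrings (0.0768 to 0.118). The glutamine list also lost it on the ratio table (0.0826) and with an intensity trend (0.0593), the transcription factors with the mean of probe sets (0.0552) and with genes of 2 lists left out (0.0529), and neutrophils with the dim filter (0.0544). Lipoprotein uptake gained a call under both median centrings (0.0129 and 0.0153), on the ratio table (0.0168), with an intensity trend (0.048), with genes of 2 lists left out (0.0203) and without pre-cancerous array 2 (0.013), against adjusted p = 0.583 with an estimated correlation. Tuft cells (0.0223) and ER chaperones (0.0226) gained one with the dim filter, ER chaperones also without pre-cancerous array 2 (0.0301) or 3 (0.00103), lysosome without pre-cancerous array 2 (0.036) and mesothelium without control array 2 (0.00247); their adjusted p was 0.583, 0.741, 0.603 and 0.583 with an estimated correlation. Given as medians, the lists that turned were: under quantile normalization mast cells -0.0089 and amino acid transporters -0.15; under median centring p53 targets -0.10 and transporters -0.21; with centring on genes in no list -0.090 and -0.20; on the ratio table mast cells -0.043, Schwann cells -0.012 and p53 targets 0.0082; with the dim filter intestinal epithelium -0.18; with an intensity trend mast cells -0.056 and p53 targets -0.023; and with genes of 2 lists left out regeneration -1.03, transporters -0.084 and hypoxia -0.050. Leaving out each array gave medians of -0.057 to 0.030 for p53 targets, -0.25 to 0.017 for transporters, -0.090 to 0.014 for mast cells, -0.044 to 1.18 for neutrophils, -0.49 to -0.016 for the synthetases, -0.58 to 0.053 for ER chaperones, -0.059 to 0.20 for NRF2 targets and -0.30 to 0.34 for islets; the cause was not tested.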

Other observations

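The values here were chosen after the data were seen, with no test beyond those named. Some single genes were at unlike levels in the 3 pre-cancerous arrays, and they were not tested as a group. Glycam1 was at 10.68 and 10.63 in pre-cancerous arrays 1 and 3 and at 5.64 in array 2, against 5.65, 5.59 and 5.75 in the controls. Mcpt2, a protease of mucosal mast cells, was at 10.01, 4.86 and 8.03 against 4.08, 4.46 and 3.94, and Mcpt1 at 8.88, 4.47 and 6.71 against 4.33, 4.97 and 4.64, while the mast cell list, which holds neither, had medians within 0.05 of 0 in the 3 arrays. Sfrp1, a secreted Wnt antagonist, was at 12.46, 7.68 and 9.76 against 7.97, 7.73 and 7.73, and Lcn2, an iron-carrier binding protein of inflamed epithelium, at 12.45, 7.67 and 9.59 against 8.13, 7.59 and 7.20. All of these had an adjusted p = 0.521 by limma.

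Other genes differed at like levels in all 3 pre-cancerous arrays. The mitotic genes Cdca8, Ttk and Kif20b had log2 fold changes of 0.90 (SE 0.10), 0.80 (SE 0.11) and 0.84 (SE 0.12), and the replication clamp Pcna of 0.87 (SE 0.13). Cyp2e1, an ethanol-oxidizing cytochrome, was at 6.09, 5.54 and 6.01 against 7.37, 6.84 and 7.59, and the phosphodiesterase Pde3b at 8.88, 8.90 and 9.02 against 9.38, 9.43 and 9.45. None passed the adjustment over all genes (adjusted p = 0.521 for each).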
